A study of Rattus norvegicus with 24 samples.

How the data were processed

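The series holds 24 CodeLink arrays of mesenteric artery cRNA from 12 rats, 4 each given vehicle, estradiol benzoate or testosterone, with 2 technical arrays of the same cRNA per animal. Per the labels, the arteries were dissected from fat, veins and connective tissue, 2 µg of total RNA was transcribed to biotin-marked cRNA, and 10 µg of cRNA was hybridised for 18 h at 37 C to CodeLink (Amersham/GE) one-colour arrays read with an Alexa dye. The deposited values are linear spot intensity, scaled by the authors so that every array median lies just below 1, with a few values at or below 0 that point to background subtraction. The scanner software, the background correction, the scaling and the spot filters are not given in the sources used here. Blank cells are spots without a value.

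Values at or below 0 (327 over all arrays, 5 to 52 per array) and blank spots were treated as missing, and log2 was taken of the rest with no pseudocount and no further scaling, since the log2 medians of the arrays spanned only 0.0441. The values of the 2 arrays of an animal were averaged on the log2 scale, so that the animal was the unit of replication. Of 10399 probes, 10228 had a value in at least 3 animals of each group and were tested. A single gene symbol was given for 7294 probes, several for 88 and none for 3017; 7284 of the first were matched to the gene reference by gene ID, which changed 0 symbols. For genes with several probes, the probe with the highest mean over the 12 animals stood for the gene.

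A group-means model was fitted with limma 3.58.1 in R 4.3.3 to all 12 animals (lmFit and eBayes with default prior, 9 residual and 2.51 prior degrees of freedom). The 3 pairs of groups were compared with two-sided tests, any difference among the groups with the moderated F test, and p was adjusted by Benjamini-Hochberg over the 10228 probes. A probe was called at an adjusted p under 0.05. Where a count was small, the probes at an unadjusted p under 0.05 were counted as well.

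Gene lists for hormone response, vascular tone, the artery wall, cell types of the vessel and of neighbouring tissue, stress, metabolism and the clock were tested with camera (preset correlation 0.01, two-sided, adjusted over the lists of a comparison). All 33 had at least 5 measured genes, and 6249 genes took part. Camera was repeated with the correlation estimated from the data, and fry, which tests whether a list moves one way on balance without comparing it with other genes, was run beside it. Both called 0 lists in each of the 3 comparisons. A list of hepatocyte genes was added after liver genes were seen, and was tested apart from the others.

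The comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took, for each pair of groups, the called genes with a single symbol, up to 10 in each direction by size of change, and filled up to 10 with the smallest unadjusted p. It added up to 4 members with the smallest p for each list described, of which up to 3 were named, as well as Esr1, Esr2, Pgr, Nos3, Acta2, Myh11, Pecam1 and abundant genes of a tissue whose list is discussed. A further gene of the rule is not reported here. Genes and probes outside the rule are said to have been mentioned after their values were seen.

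The correlation between both hormone effects was set beside 200 simulations without an effect but with shared vehicle animals, and beside splits of the vehicle animals into 2 and 2. Other divisions of the samples into groups of the same size, 35 for each pair of groups, were fitted in the same way, and 100 were drawn where more existed. Measures within groups were compared by exact permutation within groups. A sample was singled out when its gap to the nearest other value of its group exceeded the 95% Dixon value.

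The number of animals, with 2 arrays each, limits the precision, and dim probes are limited by their signal over background. The fit was tested on simulated data with the spread of these animals, 10228 probes and 500 changed ones of each size over 5 simulations. A log2 change of 1 was found in 79.8% to 82.2% of the probes and a change of 2 in 94.6% to 95.8%, over the 3 comparisons. Adjustment by Benjamini-Hochberg is less strict where many probes change at once, as in each of these simulations. These shares therefore do not hold for comparisons in which few probes pass. Beside these, 35 to 60 unchanged probes were called per comparison over the 5 simulations, and 0 to 2 probes in simulations without any change. Lists of 25 genes shifted by 0.3 were found in 5 of 5 simulations for each comparison, and an unshifted list was called in 1 of 5 for estradiol benzoate minus testosterone and in 0 for the others. Probes were drawn independently of each other in these simulations. The estimated correlation within the real lists reached 0.475 (cell cycle) and 0.445 (pancreas), so the simulations do not cover lists whose genes vary together.

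Alternatives covered the scaling between arrays, filters on dim or incomplete probes, a pseudocount of 0.0449, either duplicate alone, all 24 arrays with the animal as a random block, an intensity trend with a robust prior, array weights, a block for the number in the label, a threshold of 0.1, a fit of the 2 groups compared alone and leaving out each animal. Leaving out estradiol benzoate animal 3 and vehicle animal 5 together, testosterone animal 8 from 1 array alone, the mean of both hormone groups minus vehicle, the counts at an unadjusted p and the splits of 7 animals without estradiol benzoate animal 3 were added after the data were seen. No array was left out of the results reported. Probe sequences, control spots and the scanned images were not analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.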

Results

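Gene expression was measured in mesenteric arteries, the small arteries that feed the intestine and contribute to the control of blood pressure, from 12 ovariectomised female Sprague Dawley rats. Ovariectomy, the removal of the ovaries and with them the main source of sex steroids, was done at 3 weeks of age and was followed by 2 weeks of recovery. The rats then received daily intraperitoneal injections for 4 days. The groups were vehicle (sesame oil), estradiol benzoate (an injectable ester of the estrogen estradiol, 0.15 mg per kg per day) and testosterone (the main androgen, which tissues can also convert to estradiol, 1 mg per kg per day), with 4 animals in each. The cRNA of each animal was hybridised to 2 CodeLink arrays, one-colour oligonucleotide arrays read with 1 fluorescent dye, so that 24 arrays were available. Animals are named here by group and by the number in their label.

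The 24 arrays held values for 10399 probes, of which 10228 had a value in at least 3 animals of every group and were tested. Array medians lay between 0.926 and 0.951 and maxima between 47.4 and 82.5, with 152 to 665 blank spots per array. The 2 arrays of an animal correlated across probes with r between 0.976 and 0.993 (median 0.988). The median standard deviation (SD) of a probe was 0.119 between duplicate arrays and 0.195 between animals of a group, both on the log2 scale. The first is the SD of 1 array and the second that of the mean of the 2 arrays of an animal. In the dimmest 10% of probes the values were 0.747 between duplicates and 0.622 between animals. A single array varies more than a mean of 2, so these values do not show that duplicates differed more than animals. The number of animals, with 2 arrays each, limits the precision of every value below. Changes are log2 differences of group means with their standard error (SE) from the shared limma fit, each from 4 animals per group unless a value is missing in 1 of them, as for Esr2 with testosterone and Pbsn with estradiol benzoate.

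The first comparison asked which genes differ in the arteries of rats given estradiol benzoate against vehicle. The largest differences with the smallest p lay in a steroid-metabolising enzyme and in immediate early transcription factors. Akr1c14, a hydroxysteroid dehydrogenase, was 2.97-fold higher (log2 1.57, SE 0.24) and Junb, a subunit of the AP-1 transcription factor, 2.51-fold higher (log2 1.33, SE 0.21). Aff3, a nuclear protein of the transcription elongation machinery, was higher by 0.76 (SE 0.11). Each had 4 of 4 treated animals above the vehicle mean. None of the 10228 probes passed the limma threshold of an adjusted p under 0.05: the adjusted p was 0.0770 for Aff3 and 0.0941 for Akr1c14 and Junb, and 0.0770 was the smallest of all. At an unadjusted p under 0.05, 1376 probes were counted, 692 higher and 684 lower, where 511.4 would be expected by chance from independent probes. At an adjusted p under 0.1, 5 probes were counted, 4 higher and 1 lower, the other two being probe 13616 (1.32) and probe 4744 (-0.64), both without a gene symbol and mentioned after their values were seen. The count of 1376 was 909 without estradiol benzoate animal 3 (459 higher, 450 lower). The count of 0 became 2 without vehicle animal 5 and 1 without estradiol benzoate animal 5.

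Other genes named by the same rule are given as values, since none passed the test. Higher values were found for Egr1 (1.32, SE 0.23) and Fosb (1.13, SE 0.20), immediate early transcription factors, and for Slc38a1 (1.20, SE 0.21), a glutamine transporter. Inmt, a methyltransferase of indole amines, differed by 1.16 (SE 0.20), Il4r, the interleukin 4 receptor, by 0.94 (SE 0.17), Bhlhe40, a repressor within the circadian clock, by 0.88 (SE 0.17) and Shisa7 by 0.66 (SE 0.13). Lower values were found for Pde2a (-0.71, SE 0.12), a phosphodiesterase that degrades cyclic nucleotides, Hcrtr2 (-0.93, SE 0.17), Mc4r (-1.14, SE 0.24), Akap12 (-0.54, SE 0.10), an anchor of protein kinase A, and Prkaa2 (-0.52, SE 0.10), a catalytic subunit of AMP-activated kinase. Pi4kb (-0.57), Mycbp2 (-0.56), Slc40a1 (-0.54), Btbd16 (-0.56) and Polr2i (-0.42) completed the lower genes. In all of these genes 4 of 4 treated animals lay beyond the vehicle mean, with adjusted p from 0.122 to 0.154 in limma. Dimmer second probes gave -0.12 for Mycbp2, -0.32 for Akap12 and -0.33 for Slc40a1, and further probes of Slc38a1 gave 0.57 and 0.40.

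**Figure D1:**
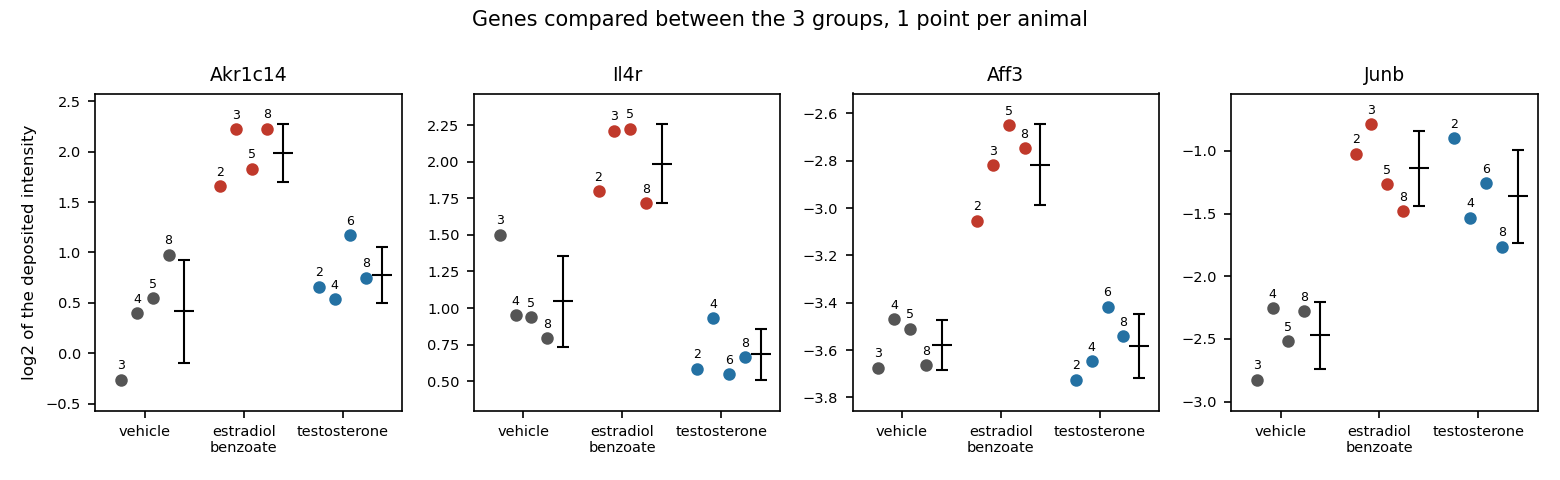
Each point is 1 animal, numbered as in its label, in the vehicle, estradiol benzoate and testosterone groups; the vertical axis is the log2 of the deposited intensity and the bar is the mean with SD (n = 4). Akr1c14 lay between 1.66 and 2.23 in the estradiol benzoate animals and between -0.26 and 0.98 in vehicle, and Il4r between 1.71 and 2.23 against 0.55 to 0.93 in testosterone.

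In the camera test 7 of the 33 gene lists rose after estradiol benzoate and none fell. The immediate early genes, which are transcribed within minutes of a stimulus, rose by a mean of 0.38, with 19 of 26 members higher, among them Junb, Egr1 and Fosb. Their adjusted p was 7.0e-05, and the adjusted p = 0.309 with an estimated correlation. The estradiol benzoate animals ranked in this list (3 at 0.33, 8 at 0.29, 5 at 0.16 and 2 at 0.04 from the mean of the 12 animals) as they did in the pancreas list below. No member passed over all probes, while 7 were higher when adjusted over the list alone. The lymphocyte list rose by 0.41 with 15 of 16 members higher, including the T cell genes Cd8a (0.96) and Cd8b (0.61) and the homing receptor Ccr7 (0.93). Its adjusted p was 1.0e-04, and adjusted p = 0.309 with an estimated correlation; 3 members were higher when adjusted over the list alone and 0 over all probes. The interferon response list rose by 0.24 (12 of 16 higher, adjusted p 0.00473), with Irf7 at 0.50, Tap1 at 0.46 and Ifit3 at 0.42. For that list the adjusted p = 0.433 with an estimated correlation, and 0 members passed over the list alone or over all probes.

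Genes of fat cells were also higher. The adipocyte and lymphocyte lists were among those set to detect RNA of neighbouring tissue, such as fat and lymph node, which dissected arteries can carry. An effect of estradiol benzoate on these lists was not tested apart from such RNA. The white adipocyte list rose by a mean of 0.37 (20 of 24 members higher, adjusted p 7.0e-05, and adjusted p = 0.340 with an estimated correlation), with 4 members higher when adjusted over the list alone and 0 over all probes. Its members with the smallest p were the lipid enzyme Agpat2 (0.41), the anaplerotic enzyme Pc (0.63) and the glycerol channel Aqp7 (0.47). The brown adipocyte list rose by 0.24 (6 of 7 higher, adjusted p 0.0168, and adjusted p = 0.309 with an estimated correlation), with Cidea at 0.47, Cpt1b at 0.55 and Slc25a20 at 0.36. In it 2 members were higher when adjusted over the list alone and 0 over all probes. The oxidative phosphorylation list rose by 0.12 (21 of 28 higher, adjusted p 0.0110, and adjusted p = 0.577 with an estimated correlation), with Sdhd and Atp5pb at 0.28 and Cox5a at 0.43. None of its members passed over the list alone or over all probes. Without vehicle animal 3 its mean was 0.10 and its adjusted p 0.0601.

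Genes of the pancreas gave the largest mean, 1.91, with 17 of 18 members higher, adjusted p 7.0e-05, and adjusted p = 0.448 with an estimated correlation. Colipase (Clps) differed by 4.08, the elastase Cela1 by 3.32 and somatostatin (Sst) by 0.45, and 1 member was higher when adjusted over the list alone and 0 over all probes. The size came largely from estradiol benzoate animal 3: its list mean was 4.25 above the mean of the 12 animals, that of animal 8 was 1.20, and animals 2 and 5 lay at -0.75 and 0.13. Without animal 3 the list mean was 0.90 with an adjusted p of 0.00191. Liver genes moved the other way. A list of 22 measured hepatocyte genes, chosen after such genes had been seen, had a mean change of -1.44 and lay lower, with 20 of 22 members lower, p 1.16e-07 in camera and p = 0.0806 with an estimated correlation. In it 0 members passed over all probes and 2 were lower when adjusted over the list alone. Vehicle animal 5 stood highest, at 2.80 above the mean of the 12 animals, followed by vehicle animals 3 and 4 at 1.16 and 0.64, while vehicle animal 8 at -0.43 lay among the hormone animals (-0.91 to -0.19). Without animal 5 the change was -0.85 with p 2.2e-06.

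Lists tied to estrogen action and to the artery wall did not pass in this comparison. The estrogen-responsive list had a mean of 0.05 with 12 of 21 members higher (adjusted p 0.318), with Fos at 1.41, Tgfa at 0.85 and Sfrp4 at -1.23, and 3 members were higher and 1 lower when adjusted over the list alone. The estrogen receptor Esr1 had a value of -0.00 (SE 0.12), Esr2 of -0.14 (SE 0.17) and the progesterone receptor Pgr of 0.19 (SE 0.26). A second, dim Esr1 probe gave -1.21. Smooth muscle contractile genes had a mean of 0.04 (adjusted p 0.734), with Rgs5 at -0.49, Pdgfrb at 0.37 and Cnn1 at -0.25. Endothelial genes had a mean of 0.00 and a median of -0.02 with a test direction of lower (adjusted p 0.778), with Ace at 0.30, Edn1 at -0.34, Tek at -0.23 and Pecam1 at -0.15 (SE 0.11). Dimmer second probes gave 0.02 for Edn1, 0.67 for Tek and 0.30 for Pecam1. Cell cycle genes had a mean of -0.24 with 20 of 27 members lower (adjusted p 0.209), with Prim1 at 0.49, Prc1 at -0.79 and Hmmr at -0.93. They passed without estradiol benzoate animal 2 (-0.37, adjusted p 0.00489) or animal 5 (-0.33, adjusted p 0.0307). The estradiol benzoate animals varied widely in this list (SD 0.41 against 0.24 in vehicle). Leaving out estradiol benzoate animal 8 makes the difference smaller, as it does between the hormones below. No probe with a single symbol was tested for Nos3, Acta2 or Myh11.

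The second comparison asked which genes differ in rats given testosterone against vehicle. Of the 5 probes that passed, 3 belonged to genes of the circadian clock, the transcriptional loop that keeps daily time. Dbp, a transcription factor driven by the clock, rose 3.90-fold (log2 1.96, SE 0.27) and Bhlhe40, a repressor within the loop, rose 2.34-fold (log2 1.22, SE 0.17). Bmal1, the activator of the loop, whose transcript peaks when that of Dbp is low, fell to 0.432 of the vehicle level (log2 -1.21, SE 0.15). Tmem86a, a lysoplasmalogenase, rose 1.85-fold (log2 0.89, SE 0.12), and probe 4744, which has no gene symbol and is mentioned after its value was seen, fell by 0.79 on the log2 scale (SE 0.09). In each of these 5, 4 of 4 testosterone animals lay beyond the vehicle mean in the direction given. The limma adjusted p was 0.0282 for Bmal1, 0.0297 for Dbp and Bhlhe40, 0.0317 for Tmem86a and 0.0197 for probe 4744. These 5 probes, 3 up and 2 down, were all that passed among 10228, and 1437 had an unadjusted p under 0.05 (677 higher, 760 lower).

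The count of 5 depended on single animals. It was 0 without vehicle animal 3, testosterone animal 2 or testosterone animal 6, 1 without testosterone animal 4 or 8, 11 without vehicle animal 8 and 45 without vehicle animal 5, of which 40 were lower and which included all 5.

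**Figure D2:**
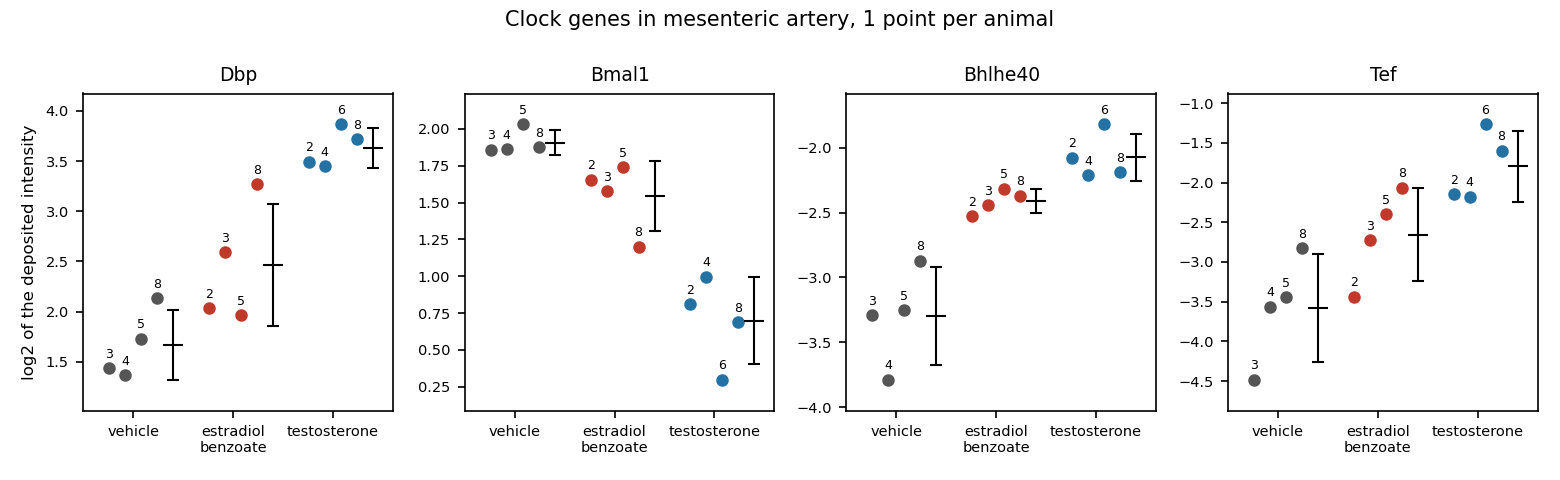
Each point is 1 animal, numbered as in its label, in the 3 groups; the vertical axis is the log2 of the deposited intensity and the bar is the mean with SD (n = 4). Dbp lay between 3.45 and 3.87 in the testosterone animals, between 1.97 and 3.27 with estradiol benzoate and between 1.37 and 2.13 in vehicle, and Bmal1 between 0.30 and 1.00, 1.20 and 1.74, and 1.86 and 2.03 in the same order.

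The circadian list as a whole had a mean of 0.46 with 9 of 12 members higher, but did not pass in camera (adjusted p 0.0723, and adjusted p = 0.404 with an estimated correlation). Camera used 11 of the members, without Nr1d2, which lacks a value in 1 animal. It tests a shift in 1 direction, while this list holds both Dbp, which rose, and Bmal1, which fell. A form of fry that ignores direction gave an unadjusted p of 4.0e-07 for this list and 2.3e-06 for the immediate early list. In it 2 members passed upward and 1 downward over all probes. When adjusted over the list alone, 4 were higher and 1 lower, the higher ones being Dbp, Bhlhe40, Tef and Nr1d2. Tef, a relative of Dbp, had a value of 1.78 (SE 0.37, 4 of 4 higher, adjusted p 0.126 over all probes), and Nr1d2, a repressor of Bmal1, a value of 1.03 (SE 0.30, 3 of 3 animals with a value higher, adjusted p 0.239). Both are mentioned after their values were seen. The list passed without vehicle animal 8 (0.55, adjusted p 0.0405), testosterone animal 2 (0.46, adjusted p 0.0272) or testosterone animal 8 (0.45, adjusted p 0.0220). After estradiol benzoate the same list had a mean of 0.26 (adjusted p 0.126).

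Other genes named in the testosterone comparison did not pass and are given as values. Higher values were found for Tcap (1.73, SE 0.32), a titin-binding protein of striated muscle, Junb (1.11, SE 0.21), Gsr (0.82), which reduces glutathione, the neuropeptide galanin (Gal, 0.56), Mc5r (0.82), Cplx1 (0.70) and Lysmd2 (0.66). Lower values were found for Pde2a (-0.76, SE 0.12), Klf4 (-0.54), a transcription factor of smooth muscle and endothelium, Hcrtr2 (-0.95), Hspa8 (-0.64), a chaperone, Btbd16 (-0.66), Adam6 (-0.41) and LOC100361261 (-0.67). The liver plasma protein genes Gc (-5.06, SE 1.07) and Fetub (-4.69, SE 0.92) had the largest values, and vehicle animal 5, which had the highest hepatocyte genes, takes part in them. All had 4 of 4 animals beyond the vehicle mean, with adjusted p between 0.109 and 0.136 in limma. The hepatocyte list lay lower by -1.70 (19 of 22 members lower, p 2.54e-07 in camera and p = 0.0879 with an estimated correlation), with 9 members lower when adjusted over the list alone and 0 over all probes. Without vehicle animal 5 its value was -1.11 with p 9.18e-07.

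Only 2 of the 33 fixed lists passed with testosterone in camera, and both rose. Both were among the lists set to detect RNA of neighbouring tissue, and an effect of testosterone was not tested apart from such RNA. The lymphocyte list rose by a mean of 0.37 (15 of 16 members higher, adjusted p 8.7e-04, and adjusted p = 0.404 with an estimated correlation), with Ccr7 at 1.23, Cd8a at 0.82 and Cd8b at 0.55. In it 3 members were higher when adjusted over the list alone and 0 over all probes. The white adipocyte list rose by 0.21 (18 of 24 higher, adjusted p 0.0267, and adjusted p = 0.830 with an estimated correlation), with Agpat2 at 0.52, Aqp7 at 0.50 and the adrenergic receptor Adrb3 at 0.49. In it 1 member was higher when adjusted over the list alone and 0 over all probes. A second Adrb3 probe gave 0.11. The white adipocyte call was lost without vehicle animal 3 (adjusted p 0.0686), vehicle animal 5 (0.123, mean 0.14), testosterone animal 2 (0.104) or testosterone animal 6 (0.134), and the number of lists was 1 without vehicle animal 3 or testosterone animal 6.

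The androgen-responsive list did not pass. Its mean was -0.03, its median 0.02 and its test direction higher (adjusted p 0.921), with the peptidase Mme at 0.73, the cell cycle inhibitor Cdkn1a at -0.71 and Azgp1 at -1.34. The immediate early list had a mean of 0.13 (adjusted p 0.408); when adjusted over the list alone 2 members were higher, Junb and Egr1 (0.74), and 2 lower, Klf4 and Klf6 (-0.74). Egr1 is mentioned here after its value was seen. Smooth muscle contractile genes had a mean of 0.03, a median of -0.02 and a test direction of higher (adjusted p 0.921), with Tpm1 at 0.35, Vcl at 0.31 and Itga8 at -0.18. Endothelial genes had a mean of -0.04 (adjusted p 0.644), with Sox17 at -0.37, Ace at 0.36 and Tek at -0.21. Dimmer second probes gave 0.20 for Sox17 and 0.71 for Tek. Pancreas genes had a mean of 0.20 (adjusted p 0.470). Testosterone animal 6 stood highest in them, with 9 of 18 members over 1 above the other testosterone animals (median of all 1.15). The values of Esr1, Esr2, Pgr and Pecam1 were 0.11, -0.27, -0.51 and -0.04.

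The third comparison set the hormones against each other. Il4r, the receptor subunit for interleukin 4 and interleukin 13, was 2.47-fold higher with estradiol benzoate than with testosterone (log2 1.31, SE 0.17) and Aff3 1.70-fold higher (log2 0.77, SE 0.11). Probe 6728, which has no gene symbol and is mentioned after its value was seen, was higher by 1.18 (SE 0.16). All 3 had 4 of 4 estradiol benzoate animals above the testosterone mean. The limma adjusted p was 0.0431 for Il4r and probe 6728 and 0.0461 for Aff3. No probe was lower, and 422 had an unadjusted p under 0.05 (247 higher, 175 lower). At an adjusted p under 0.1 the polycomb protein Rybp (0.62, SE 0.09, adjusted p 0.0726) and the collagen lysyl hydroxylase Plod2 (0.62, SE 0.10, adjusted p 0.0898) were also higher, in 4 of 4 animals. The count of 3 was 0 without any one of the 4 estradiol benzoate animals or of testosterone animals 2, 4 and 6, and 1 without testosterone animal 8.

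Among the genes that did not pass, the clock genes that changed with testosterone had values of 0.85 (Bmal1, SE 0.15, adjusted p 0.219) and -1.17 (Dbp, SE 0.27, adjusted p 0.337) for estradiol benzoate minus testosterone, so a difference between the hormones was not established for them. Akr1c14 had a value of 1.20 (SE 0.24), Inmt of 1.03, Atosa of 0.79, Insyn1 of 0.68 and Raly of 0.65. Lower values were found for Ptgfr (-1.20, SE 0.22), the receptor for prostaglandin F, the matrix proteoglycan Bcan (-1.17), Tmem178a (-0.61), Dcx (-0.60), Vipr2 (-0.58), a receptor for vasoactive intestinal peptide, Prr5l (-0.57), Fancc (-0.37) and Rasl10a (-0.35). Cyp7b1, an oxysterol hydroxylase, had a value of -0.47. Pgr had a value of 0.70 (unadjusted limma p 0.0198, adjusted p 0.999), Esr1 of -0.11, Esr2 of 0.13 and Pecam1 of -0.11.

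For the gene lists, 9 of 33 passed in camera between the hormones, 7 higher and 2 lower with estradiol benzoate. Immediate early genes were higher by a mean of 0.24 (19 of 26 members, adjusted p 2.5e-06, and adjusted p = 0.203 with an estimated correlation), with Fosb at 0.73, Ier2 at 0.42 and Klf4 at 0.38. Glucocorticoid-responsive genes were higher by 0.29 (9 of 10 members, adjusted p 0.00474, and adjusted p = 0.203 with an estimated correlation), with Cdkn1a at 0.81, Cebpd at 0.52 and Pdk4 at 0.35. In each of these lists 1 member was higher when adjusted over the list alone and 0 over all probes. Cell cycle genes were lower by a mean of -0.30, with 26 of 27 members lower, adjusted p 5.7e-06, and adjusted p = 0.526 with an estimated correlation. Their members with the smallest p were the mitotic genes Kif2c (-0.27), Prc1 (-0.60) and Spc25 (-0.54), and 0 passed over the list alone or over all probes. Without estradiol benzoate animal 8 the cell cycle mean was -0.13 with an adjusted p of 0.0998.

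Several lists of immune and stress genes differed by small means. Macrophage genes were higher by 0.14 (16 of 21 members, adjusted p 0.00474, and adjusted p = 0.559 with an estimated correlation), with Lgals3 at 0.38, C1qa at 0.32 and Ctss at 0.31. Chaperone genes were higher by 0.11 (18 of 26, adjusted p 0.00474, and adjusted p = 0.238 with an estimated correlation), with Sdf2l1 at 0.58, Hspb7 at 0.43 and Pdia3 at 0.18. Dimmer probes gave 0.08 for Hspb7 and 0.03 and -0.07 for Pdia3. Oxidative phosphorylation genes were higher by 0.07 (23 of 28, adjusted p 0.00601, and adjusted p = 0.559 with an estimated correlation). Inflammatory mediators were higher by 0.09 (23 of 32, adjusted p 0.0456, and adjusted p = 0.413 with an estimated correlation), with Spp1 at 0.69, Ccl11 at 0.62 and Cxcl12 at 0.43. Mast cell genes were lower by -0.13 (9 of 11, adjusted p 0.0456, and adjusted p = 0.526 with an estimated correlation), with the proteases Cpa3 at -0.46 and Mcpt4 at -0.44, and the prostaglandin D synthase Hpgds at 0.45. Adjusted over the list alone, 1 inflammatory mediator was higher and no member of the other 4 lists passed, and over all probes none passed. The macrophage call was lost without estradiol benzoate animal 3 (0.20) or testosterone animal 2 (0.198), the chaperone call without testosterone animal 8 (0.111), and the oxidative phosphorylation call without estradiol benzoate animal 3 (0.0735) or testosterone animal 2 (0.0671) or 8 (0.265), each an adjusted p. The inflammatory call was lost without estradiol benzoate animal 2 (0.0775) or 3 (0.389) or testosterone animal 2 (0.142) or 6 (0.147), and the mast cell call without estradiol benzoate animal 2 (0.198) or 5 (0.106) or testosterone animal 2 (0.172) or 8 (0.293).

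Pancreas genes were again higher with estradiol benzoate, by a mean of 1.71 (15 of 18 members, adjusted p 1.2e-05, and adjusted p = 0.526 with an estimated correlation), with the phospholipase Pla2g1b at 4.14, Clps at 3.63 and Cela1 at 3.01, and 0 members passed over the list alone or over all probes. Estradiol benzoate animal 3 again had the largest share: without it the mean was 0.70 with an adjusted p of 0.00772. The hepatocyte list had a value of 0.26 with p 0.724 between the hormones. The estrogen-responsive list had a mean of 0.20 (adjusted p 0.131), with S100g at 1.55, Gja1 at 0.44 and Sfrp4 at -1.12, and passed without estradiol benzoate animal 5 (0.28, adjusted p 0.0344). The androgen-responsive list had a mean of 0.01 (adjusted p 0.526), with Cdkn1a at 0.81, Herc3 at 0.39 and Pbsn at -0.96. White adipocyte genes had a mean of 0.16 (adjusted p 0.124) and passed without estradiol benzoate animal 5 (0.0344), testosterone animal 2 (0.0417) or testosterone animal 6 (0.00530). Smooth muscle, endothelial, lymphocyte and circadian genes had adjusted p of 0.869, 0.668, 0.869 and 0.281.

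**Figure D3:**
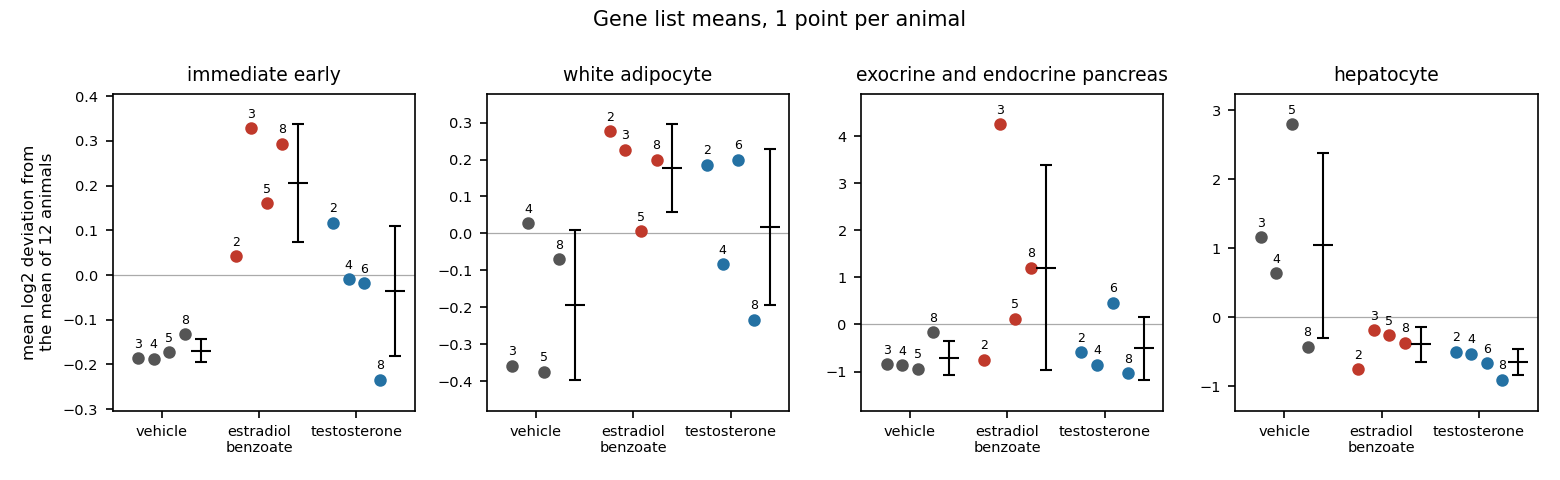
Each point is the mean over the members of a gene list in 1 animal, as the log2 deviation from the mean of the 12 animals, for the 3 groups; the bar is the group mean with SD (n = 4). Immediate early genes had group means of -0.17 ± 0.03 in vehicle and 0.21 ± 0.13 with estradiol benzoate (SD), pancreas genes reached 4.25 in estradiol benzoate animal 3 and hepatocyte genes 2.80 in vehicle animal 5.

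Asked whether any group differed, the limma F test passed 1 probe, probe 4744 (adjusted p 0.0437), with 13 at an adjusted p under 0.1 and 1218 at an unadjusted p under 0.05. Its values were -0.64 with estradiol benzoate and -0.79 with testosterone. Without single animals the F count was 32 (vehicle 5), 14 (vehicle 8), 3 (estradiol benzoate 2 or 8), 2 (testosterone 8) or 0 (vehicle 4, estradiol benzoate 3, testosterone 2, 4 or 6).

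The changes with estradiol benzoate and with testosterone, each against vehicle, correlated across the 10228 probes with r 0.732 (jackknife SE over animals 0.125). Probes are not independent replicates, and the comparisons share their 4 vehicle animals, which alone gives a correlation. With no hormone effect, 200 simulations gave a mean r of 0.50 and a highest of 0.557, and the covariance was 0.0891 against 0.0307 simulated. With separate vehicle animals for each hormone, 2 and 2, r was 0.338 on average (0.281 to 0.392) and the covariance 0.0522 (0.0440 to 0.0591). Hepatocyte genes were higher in vehicle animals 3, 4 and 5 than in the hormone animals. Both sides of every split included such an animal, so these genes still lay lower with both hormones. The correlation left in the splits was not tested apart from them. Of the probes with an unadjusted p under 0.05 in both comparisons, 340 were higher in both, 334 were lower in both and 3 had opposite signs. Comparisons without shared animals would give 45.8 and 50.8 by chance. Among as many probes of smallest p, the simulations with shared vehicle animals and independent probes gave 209.0 higher in both (highest 242) and 224 lower in both (highest 264) on average. Among single genes, Junb had values of 1.33 and 1.11, Pde2a of -0.71 and -0.76, Hcrtr2 of -0.93 and -0.95 and Bhlhe40 of 0.88 and 1.22 with estradiol benzoate and testosterone.

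**Figure D4:**
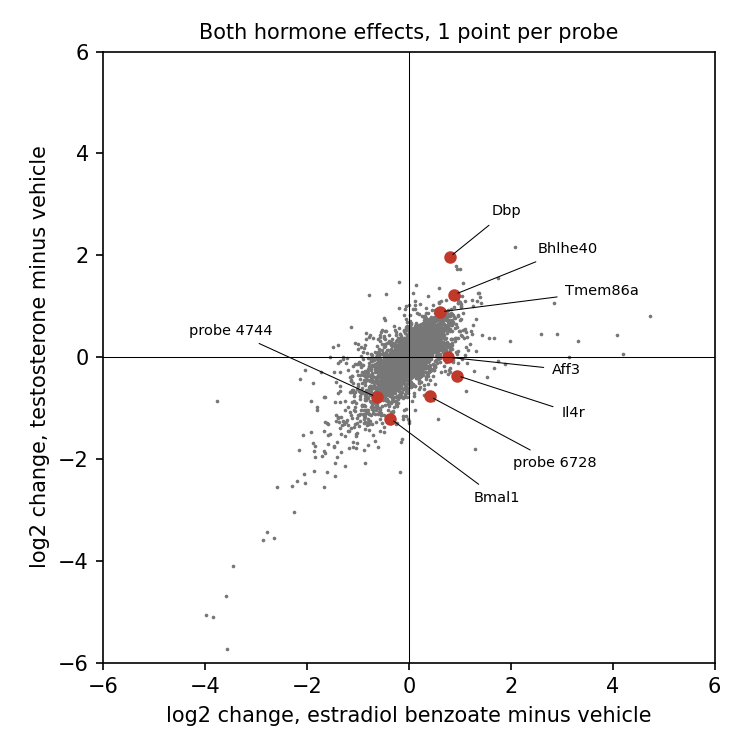
Each point is 1 of 10228 probes, with its log2 change in estradiol benzoate minus vehicle on the horizontal axis and in testosterone minus vehicle on the vertical axis; red points are the probes that passed in any pair of groups. The correlation was 0.732, and Dbp (0.80 and 1.96) and Bmal1 (-0.36 and -1.21) lay farther along the testosterone axis.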

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

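The splits of the samples for called probes of the pairs of groups were set in advance. Those for the F test, for lists and for probes at an unadjusted p were added once the real counts were known but before any split was fitted, and the correlation of immediate early with chaperone genes was set before its value was seen. The tests of the clock arms, the scaling of Dbp, the time of day, the pancreas and liver genes, the split of the immediate early list, its correlation with the pancreas list and the splits without estradiol benzoate animal 3 were chosen after the results were seen.

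Clock genes differed between testosterone and vehicle animals. The output genes of the clock differed from the arm of Bmal1 by 1.78 on the log2 scale (highest of the other splits 1.33, 1 of 35 as large), which does not exclude chance because these genes were chosen after Dbp and Bmal1 were seen to change. The circadian list fixed in advance had an adjusted p of 0.0723 in camera, which tests a shift in 1 direction and so says little about arms that move apart. Under 3 other scalings of the arrays the change of Dbp was at least 1.95. The log2 medians of the deposited arrays spanned only 0.0441, so rescaling had little to move and this test could hardly have come out otherwise. The hour at which tissue was taken could account for the pattern, since the arms of the clock also opposed each other between animals of the same group (within-group r -0.59 over 12 animals, exact permutation p 0.0565, adjusted 0.0928; rho -0.62, p 0.0537; r -0.78 without the 2 animals farthest from the median). That hour is not given in the sources used here, and with an adjusted p of 0.0928 the time of day and an effect of testosterone cannot be told apart. The effect of testosterone itself stays open and was not tested apart from the time of day.

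Genes of other organs stood out in single animals, those of the exocrine pancreas in estradiol benzoate animal 3 and those of the liver in vehicle animal 5. In animal 3 Pnlip, Cpa1 and Cela1 reached log2 values of 5.18, 4.37 and 3.54, 6.89, 5.72 and 5.57 above the other estradiol benzoate animals, with the acinar gene Spink1 at -0.05 and the islet genes Ppy, Sst, Iapp and Gcg between -0.24 and 0.15; in vehicle animal 5 Gc, Fabp1, Apoa2 and Alb reached 3.76, 3.42, 3.08 and 1.65, and of 22 hepatocyte genes, chosen after liver genes had been seen, 16 rose by over 1 (median of all 2.88), as liver RNA could give, while Hrg, Slc10a1, Plg, Tat, Apob and Cyp2c11 lay between -0.46 and 0.36. For pancreas RNA, 10 acinar genes outside the list were required to rise by a median above 1, and a median below 0.5 was to count against it; the median was 0.163, which counts against it, but the bound is judged wrong from the values, since Sycn and Zg16 rose by 4.22 and 6.04 while the other 8, several of them not specific to acinar cells, lay between -0.11 and 0.53, so pancreas RNA and a response of that animal cannot be told apart. Without these animals camera with its preset correlation gave an adjusted p of 0.00191 for the pancreas list after estradiol benzoate. For the hepatocyte list it gave p 2.2e-06 or smaller in both hormone groups. With an estimated correlation and all animals the pancreas list had an adjusted p of 0.448 and the hepatocyte list p of 0.0806 and 0.0879. The correlation was not estimated without these animals. An effect of estradiol benzoate on pancreas genes, or of the hormones on liver genes, and traces of the organ in further animals therefore cannot be told apart. In the fixed pancreas list 13 of 18 members rose by over 1 above the rest of the group in estradiol benzoate animal 3. So did 9 in testosterone animal 6 and 4 in vehicle animal 8, neither given estradiol benzoate. Some liver genes flat in vehicle animal 5 had a dimmer second probe. Against vehicle, it gave -2.21 with estradiol benzoate and -2.43 with testosterone for Slc10a1. Plg gave -0.84 and -0.76, Apob -0.93 and -0.15 and Tat 0.10 and 0.11 in the same order. Arrays of the organs themselves, which would settle the source, are not among these samples.

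Immediate early genes were higher in estradiol benzoate than in vehicle animals by a list mean of 0.38 (highest of the other splits 0.288, 1 of 35 as large), which does not exclude chance, because the list was singled out after its result was seen and its adjusted p was 0.309 with an estimated correlation. Handling or delay during dissection could raise such genes. It was assumed in advance that it would also raise chaperone genes in the same animals, and this assumption was not tested. Within groups the lists correlated with r 0.281 over 12 animals (exact permutation p 0.456, adjusted 0.456; rho 0.0350, p 0.935), and with -0.365 without the 2 animals farthest from the median, which leaves handling and an effect of estradiol benzoate such that they cannot be told apart. The list also followed the pancreas list within groups (r 0.632 over 12 animals, exact permutation p 0.0618, adjusted 0.0928; rho 0.769, p 0.0396; r 0.389 without the 2 animals farthest from the median), so tissue of the pancreas in the preparations and an effect of estradiol benzoate cannot be told apart either, with a list mean of 0.33 (adjusted p 9.7e-05 in camera) without estradiol benzoate animal 3. The effect of estradiol benzoate stays open and was not tested apart from handling or other tissue.

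The counts of probes and lists were set beside other splits of the same animals. For estradiol benzoate against vehicle the splits say nothing about the 0 called probes, since every split has at least as many (35 of 35, highest other 0). Chance is not excluded for the 7 lists (2 of 35, highest other 7). No other split reached the 1376 probes at an unadjusted p under 0.05 (1 of 35, highest other 1099). Without estradiol benzoate animal 3, however, the count was 909 and chance is not excluded (3 of 35, highest other 1226). Without it and vehicle animal 5 together the count was 864. The count was 992 without vehicle animal 3 and 1065 without estradiol benzoate animal 8, and no splits were fitted without those animals. For testosterone against vehicle, with all animals, the 5 called probes were more than in any other split (1 of 35, highest other 2). Chance is not excluded for the 1437 probes (2 of 35, highest other 1718) or the 2 lists (20 of 35, highest other 7). For estradiol benzoate against testosterone, with all animals, the 3 called probes were more than in any other split (1 of 35, highest other 0). Chance is not excluded for the 422 probes (13 of 35, highest other 906) or the 9 lists (5 of 35, highest other 10). For the F test, with all animals, 3 of 100 splits, the real one included, called at least 1 probe (highest other 2). A share of 1 of 35 is the smallest that 35 splits can give. The shares were not adjusted over the split tests, so chance is not excluded for these called probes either. Their counts also rest on single animals. The count was 0 without any one of 3 animals for testosterone against vehicle, of 7 animals between the hormones and of 5 animals for the F test. Between the hormones it was also 0 in a fit of the 2 groups alone. The split with 1718 probes set vehicle animals 3, 5 and 8 with testosterone animal 8 against the rest.

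Among 418 groups of 4 values, 19 held a value whose gap to the nearest other exceeded the Dixon bound, where 20.9 were expected, since chance flags about 1 in 20 groups. In the vehicle group the gaps on the log2 scale were 0.16 for Bmal1 and -0.54 for Cd8b in animal 5, 0.62 for Fos, 0.44 for Pde2a and 0.67 for the pancreas list mean in animal 8, -0.53 for Slc25a20 in animal 3 and 0.55 for Tgfa in animal 4. With estradiol benzoate they were -0.23 for Adam6 in animal 8, 0.26 for Esr1 and -0.15 for the glucocorticoid-responsive list mean in animal 2, -0.47 for Mme and -0.25 for Tmem86a in animal 5, and -0.31 for Pecam1 in animal 3. With testosterone they were 0.11 for Adam6, 3.24 for Clps and 0.36 for Mycbp2 in animal 6, and -0.15 for Atp5pb, 0.59 for Mcpt4 and -0.21 for Pde2a in animal 8. Positive gaps are values above the other 3 animals and negative gaps values below them.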

How the results depend on the processing

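Leaving out estradiol benzoate animal 3 with vehicle animal 5, and taking testosterone animal 8 from its AB array alone, were tests chosen after the results were seen. Called genes kept their direction in every setting in which they had a value. Over the settings Dbp with testosterone ranged from 1.86 to 2.12 (past the threshold in 15 of 24, adjusted p 1.3e-05 to 0.193), Bmal1 from -1.34 to -1.03 (19 of 25, 3.9e-06 to 0.190), Bhlhe40 from 0.94 to 1.39 (13 of 22, 0.00110 to 0.250) and Tmem86a from 0.66 to 1.11 (12 of 23, 0.0113 to 0.250). Against testosterone Il4r ranged from 1.11 to 1.40 (10 of 25, 2.7e-05 to 0.512) and Aff3 from 0.54 to 0.84 (5 of 23, 0.00560 to 0.512). Of the 3793 values of named genes under other settings, 3618 kept direction and side of the threshold, 68 lost the call (all in these 6 genes), 92 gained it, 15 moved and 0 reversed; of the values of the lists 504 were the same, 80 weaker, 12 stronger and 25 moved. Signal over background limits dim probes, such as the second one for Esr1: the median SD between duplicate arrays was 0.747 in the dimmest 10% and 0.119 over all probes.

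Counts of called probes are given for estradiol benzoate against vehicle (0), testosterone against vehicle (5), both hormones against each other (3) and the F test (1), in that order, where they moved. Quantile scaling gave 8 (with all 5), 0 and 7 for the last 3. Median centring and cyclic loess gave 3 and 7 for the F test, and cyclic loess gave 2 up and 4 down against 3 up and 2 down for testosterone. Without the dimmest 25% of probes the counts were 3, 2 and 8 for the F test, and without the dimmest 50% 5, 2, 5 and 9, with fewer probes tested. Probes with values on all 24 arrays gave 2, 3 and 6 for the F test, and the pseudocount 13 for the F test. The AA arrays alone gave 1, 3, 1 and 0, with 1 of the 5 testosterone calls, and the AB arrays 0 between the hormones and 6 for the F test. All 24 arrays with the animal as a random block gave 226, 151 (with all 5), 40 and 254, a setting that uses 1 correlation between duplicates (0.631) for all probes. A trend with a robust prior gave 3, and 12 for the F test. Array weights gave 13 between the hormones and 2 for the F test. A replicate block gave 0 for testosterone, 0 between the hormones and 0 for the F test. The labels give no pairing of animals, and animals of the same number correlated with r of -0.166, 0.114 and 0.147 (vehicle and estradiol benzoate), -0.102 and 0.115 (vehicle and testosterone) and 0.501 and 0.0181 (both hormones), the same number being the best match in 3 of 7 cases. A threshold of 0.1 gave 5, 5 between the hormones and 13. A fit of only the 2 groups compared gave 1 for testosterone and 0 between the hormones, with fewer animals for the spread. Without estradiol benzoate animal 3 and vehicle animal 5 together the counts were 29 for testosterone and 0 between the hormones, and with the AB array of testosterone animal 8 alone 0 between the hormones. Except for fewer probes or animals, the cause was not tested.

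Probes at an unadjusted p under 0.05 (1376, 1437 and 422) were 736 (288 higher, 448 lower), 640 (174 and 466) and 225 (160 and 65) without the dimmest 50% of probes, and between the hormones 734 with array weights and 634 with a replicate block.

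Leaving out 1 animal gave 0 to 2, 0 to 45, 0 to 1 and 0 to 32 called probes. Lists past the threshold (7, 2 and 9) were 0, 0 and 0 with an estimated correlation and also with fry. For testosterone they were 5 with the AA arrays, 0 with the AB arrays, 1 with the AB array of testosterone animal 8 alone and 1 to 3 without 1 animal. The correlation of the hormone effects (0.732) was 0.338 with separate vehicle animals, which takes away the shared controls and also leaves fewer vehicle animals per comparison, and 0.665 to 0.788 without 1 animal.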

Other observations

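The comparison of both hormone groups together with vehicle, the splits that test it and the count of dim spots were tests chosen after the results were seen.

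Averaged over both hormones, 5 probes passed in limma, 3 up and 2 down, where 1768 had an unadjusted p under 0.05 (868 higher, 900 lower). Junb rose by 1.22 (SE 0.18), Bhlhe40 by 1.05 (SE 0.14) and Tmem86a by 0.75 (SE 0.11), each with an adjusted p of 0.0483. Pde2a, a phosphodiesterase that degrades cyclic nucleotides, fell by 0.73 (SE 0.11, adjusted p 0.0483) and probe 4744 fell by 0.71 (SE 0.08, adjusted p 0.0125). In Junb, Bhlhe40 and Pde2a 4 of 4 animals of each hormone group lay beyond the vehicle mean. The count was 65 without vehicle animal 5 (11 up, 54 down), 18 without vehicle animal 8, 13 without vehicle animal 4, 4 without testosterone animal 8, 2 without estradiol benzoate animal 2, 1 without estradiol benzoate animal 3, 5 or 8 or testosterone animal 2 or 4, and 0 without vehicle animal 3 or testosterone animal 6. Without estradiol benzoate animal 3 and vehicle animal 5 together it was 14. In other settings it ranged from 0 (replicate block) to 10 (cyclic loess, or a trend with a robust prior), with 1 for probes with values on all 24 arrays or for testosterone animal 8 from its AB array alone, 2 with array weights or without the dimmest 50% of probes and 9 with a pseudocount, and 46 passed at an adjusted p under 0.1. Among 100 drawn splits into 4 and 8 animals, the real one included, 2 gave as many called probes (highest other 6) and 1 as many at an unadjusted p under 0.05 (highest other 1465). Chance is not excluded by these splits, because the comparison was chosen after both hormone effects were seen to correlate.

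Genes of vascular signalling that were not described above showed single values without a list difference, and these lists were picked for description after their values were seen. After estradiol benzoate the vasodilator peptide adrenomedullin (Adm) had a value of 0.77 (SE 0.16, 4 of 4 higher, adjusted p 0.125 in limma), Vipr2 of -0.62 (SE 0.16), angiotensinogen (Agt) of 1.01 (SE 0.27) and the calcium channel subunit Cacna1d of -1.40 (SE 0.40). The vasodilator, vasoconstrictor and ion channel lists had adjusted p of 0.734, 0.340 and 0.782, and the collagen and matrix list, with Postn at -0.60 and Plod2 at 0.40, an adjusted p of 0.653. The fibroblast list had a mean of -0.22 with 13 of 19 members lower (adjusted p 0.296), and 2 members were higher and 4 lower when adjusted over the list alone.

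On the AA array of testosterone animal 8, 39 probes with a mean log2 value above -1 lay more than 2 below the AB array, and the identifiers of all 39 ended in 44 to 48, as did those of 1031 tested probes (10.1%). The same held for 10 of 10 such probes in estradiol benzoate animal 5, 3 of 3 in estradiol benzoate animal 8 and in vehicle animal 8 and 5 of 5 in testosterone animal 4. The reverse, a value more than 2 lower on the AB array, was found for 1 probe each in testosterone animal 4 (Grip2) and vehicle animal 4 (Tns3), and only the identifier of the latter had such an ending.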
